A study of Homo sapiens with 12 samples.

How the data were processed

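Transcript levels were measured on Affymetrix Human Gene 2.0 ST arrays in LNCaP cells, an androgen-responsive human prostate cancer line, carrying a control plasmid. Cells were kept in charcoal-stripped or in full serum and received vehicle (ethanol), 1 nM cabazitaxel or 1 nM docetaxel for 16 h. The labels give 12 arrays in 6 groups of 2, numbered as replicates. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples.

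The deposited values are array intensities that the authors normalised with RMA, per the submitters' processing notes, which state no version. A check of the values showed that they are on a linear scale, from 17.32 to 6307.3, with a median of 22.31, and that 57.5% of them lie below 24. All values therefore sit above a floor, and changes of weakly expressed genes are compressed. The medians of the 12 arrays ranged from 22.19 to 22.43. Arrays give no read depth, and their number limits the precision. The submitters mention a filter on low-expressing genes without its threshold, and the deposited table held 44629 transcript clusters.

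The log2 of each value was taken. The annotation at hand named 15835 transcript clusters with 1 gene symbol each, and the other 28794 were left out of the gene tests. Where a gene had more than 1 transcript cluster, as 651 genes did, the cluster with the highest mean over the 12 arrays was kept, which gave 14812 genes. The 11105 genes with at least 2 arrays above the median of all values were tested. The annotation did not name tubulin genes, replication histones, TMPRSS2, CDKN1A, MDM2 or ABCB1, so these genes were not analysed here. XIST and Y-linked genes are not named here, and the gene tests applied no separate filter to them.

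Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and all 12 arrays in a single fit, which left 6 residual degrees of freedom and 5.08 prior degrees of freedom. There were 12 comparisons. Each drug was compared with vehicle, and the drugs with each other, within each serum and as the mean of both sera. Full serum was compared with charcoal serum in vehicle-treated cells, and each drug's effect was compared between the sera as an interaction. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Intervals are 95% confidence intervals of limma. Changes are given as log2 differences, with the standard error (SE) where it is printed.

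Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 28 lists that had tested members, out of 30. Many listed genes were not named or not tested, so the lists were covered in part. Tested were 20 of 40 androgen-induced, 7 of 18 androgen-repressed, 31 of 44 DNA replication and 36 of 44 mitosis genes. Of p53 targets 20 of 34 were tested, of NF-kappaB genes 10 of 22 and of fibroblast markers 3 of 13. Fry tests whether a list's genes move, on balance, 1 way, and does not compare the list with other genes. The members of a list were also adjusted over the list alone. In 100 simulations of unchanged groups with the correlation between genes found in these arrays, for cabazitaxel against vehicle as the mean of both sera, camera at the preset correlation called the chromatin modifier list in 31%, DNA replication in 26%, androgen-induced and mitosis genes in 18% each, and small RNAs and cholesterol synthesis in 14% each. It called the fatty acid list in 2% and the DNA repair, p53, NF-kappaB and fibroblast lists in 0%. With an estimated correlation it called each of the 28 lists in 0%. No changed list was simulated, so how many real list changes that test misses was not measured, and both are printed.

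The gene tests were tested on simulated data with 200 changed genes. At a log2 change of 0.25, 0.5 and 1, comparisons of 2 against 2 arrays recovered at most 0.15%, 64.1% and 96.9% of them. Comparisons of the mean of both sera recovered at most 17.2%, 88.1% and 99.4%, and the interactions at most 0%, 17.4% and 86.9%. The mean number of false calls was at most 12.1. Noise was drawn independently for each gene and array, so deviations shared between arrays or genes were not simulated, and recovery in the real arrays can differ.

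The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule names, among the called genes whose arrays do not overlap between groups, the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 genes were called in a direction, it names the 5 with the smallest unadjusted p, which did not pass. Small RNA and uncharacterised symbols were counted and not named by that part. Genes printed below as those with the smallest p are therefore the ones outside such symbols. It also names up to 4 members of each list with the smallest p, and a fixed set of genes. Within a single serum and for the interactions, only the first 2 of such genes in each direction are printed, list members are printed for lists that camera called or that bear on the drugs, and KLK3, FKBP5, CCNB1, PLK1, MKI67 and HMGCS1 are summarised as a range.

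The alternatives were no filter, a stricter filter on the mean above percentile 75, all transcript clusters, a repeated quantile normalisation, arrays centred on their median, a trended robust fit, array weights, only the groups compared in the fit, a replicate block, the test in the submitters' notes, and leaving out each array in turn. Alternatives chosen after seeing the data were the log2 of the value minus an assumed offset of 16, full against charcoal serum as the mean of 3 treatments, either taxane against vehicle, and exact permutation tests of list means. The closing section gives their effect.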

Results

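The 12 arrays covered 6 groups of 2, from vehicle, cabazitaxel and docetaxel in charcoal-stripped serum, which is depleted of steroid hormones, and the same treatments in full serum. Both drugs are taxanes, which bind and stabilise microtubules, and cabazitaxel carries methoxy groups at a pair of positions where docetaxel has hydroxyl groups. Across genes, the replicates of a group correlated with r from 0.9863 to 0.9922, and their log2 values differed with an SD of 0.141 to 0.184. Drug and serum groups were compared over 11105 genes, of which chance alone would bring 555 to an unadjusted p under 0.05 in each comparison.

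Full serum was compared with charcoal serum in vehicle-treated cells to show what the serum did without a drug. Classic androgen-induced genes were higher in full serum. TARP (transcript cluster 17056817), an androgen-regulated transcript of the T-cell receptor gamma locus in prostate cells, rose 3.62-fold, from a log2 intensity of 4.82 ± 0.071 to 6.68 ± 0.026 (SD, n = 2 arrays each). KLK2 (16864628), a kallikrein protease of prostate epithelium, rose 3.07-fold, from 6.73 ± 0.24 to 8.35 ± 0.23 (SD, n = 2 arrays each). KLK3 (16864616), which encodes prostate-specific antigen, rose 2.16-fold, from 9.27 ± 0.21 to 10.38 ± 0.2 (SD, n = 2 arrays each). The chemokine gene CCL2 went the other way, from 6.41 ± 0.11 to 5.39 ± 0.05 (SD, n = 2 arrays each), as did the sestrin genes SESN1 and SESN3, which belong to stress responses. The folds depend on whether the deposited values hold a constant offset, and with an assumed offset of 16 subtracted, a setting chosen after the data were seen, they were 7.04 for TARP, 3.45 for KLK2 and 2.19 for KLK3.

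Of the 20 androgen-induced genes tested, 18 were higher in full serum, with a median log2 change of 0.455. Limma called 7 of them higher over all genes, namely KLK2 (1.62), KLK3 (1.11), CENPN (0.86), HERC3 (0.85), ZBTB10 (0.76), ELOVL5 (0.58) and HOMER2 (0.56). Adjusted over the list alone, 15 were higher and 1, the keratin gene KRT18 (-0.20), was lower. Camera gave the list an adjusted p of 7.84e-25, with an adjusted p = 0.0634 with an estimated correlation, and fry gave 0.00517. FKBP5, a cochaperone gene induced by androgen, had a log2 change of 0.28 and did not pass (limma adjusted p = 0.463), with 0.13 without full-serum vehicle replicate 2, 0.43 without full-serum vehicle replicate 1 and 0.56 with the assumed offset of 16 subtracted. Of the 7 androgen-repressed genes, 6 were lower, with a median of -0.0648, and the list did not pass (camera adjusted p = 0.0583), with a median of -0.185 once the offset was subtracted.

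Limma called 44 genes between the sera, 25 higher and 19 lower in full serum, and 952 genes had an unadjusted p under 0.05. The called genes included 2 small RNA or uncharacterised symbols. The arrays of all 44 did not overlap between the sera, which chance gives for 33.3% of unselected genes. These genes were called on the same arrays, so the lack of overlap follows largely from the call and adds no support. The largest rises were those of TARP (1.86, SE 0.101, adjusted p = 1.35e-05), KLK2 (1.62, SE 0.159, adjusted p = 0.00142) and KLK3 (1.11, SE 0.176, adjusted p = 0.0231). They were followed by the orphan receptor gene GPR158 (0.99), MALT1 (0.97), which encodes a protease of NF-kappaB signalling, and SNAI2 (0.88), a transcription factor gene of epithelial-mesenchymal transition. STK39 (0.86), CENPN (0.86), HERC3 (0.85) and ABHD2 (0.80) completed the 10 largest. The largest falls were those of CCL2 (-1.02, SE 0.115, adjusted p = 0.00324), TLL1 (-0.89), SESN3 (-0.81), SESN1 (-0.75), CD24 (-0.75), SLFN5 (-0.69), LASP1 (-0.67), USP54 (-0.62), TRIQK (-0.61) and TP53INP1 (-0.60). The number of calls rested on single arrays, with 7 without charcoal vehicle replicate 2, 14 without charcoal vehicle replicate 1, 14 without full-serum vehicle replicate 2 and 43 without full-serum vehicle replicate 1. CENPN, HERC3, KLK2, LASP1, STK39, TARP and ZBTB10 were called in each of these fits, while KLK3 kept a log2 change of 0.97 to 1.26 and was not called in 3 of them, with adjusted p of 0.188, 0.0633 and 0.184 in the order of the first 3 arrays above. With the assumed offset of 16 subtracted, KLK3, ABHD2, ELOVL5, HOMER2, CLSPN, SESN1, SESN3, CD24, SLFN5, USP54, TRIQK, TP53INP1 and NFKB1 were not called (adjusted p from 0.065 to 0.187), and SNAI2 stood at 1.53.

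Genes of DNA replication were also higher in full serum, by a median log2 of 0.108, with 26 of 31 higher. CLSPN (0.53), a replication checkpoint gene, was called, and CDC45 (0.43), a helicase subunit gene, was not (limma adjusted p = 0.0822). The list's camera adjusted p was 8.32e-06, with an adjusted p = 0.354 with an estimated correlation. Among 20 p53 target genes, 14 were lower, and TP53INP1 and SESN1 were called lower (camera adjusted p = 0.00447, and adjusted p = 0.18 with an estimated correlation). Among 10 NF-kappaB and inflammatory genes, CCL2 and NFKB1 (-0.59) were called lower (camera adjusted p = 0.00447, and adjusted p = 0.166 with an estimated correlation). Among 14 genes of fatty acid synthesis, the elongase gene ELOVL5 was called higher (camera adjusted p = 0.00359, and adjusted p = 0.321 with an estimated correlation). Without full-serum vehicle replicate 2, the camera adjusted p of these last 3 lists became 0.082, 0.123 and 0.123.

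Small Cajal body and other small RNAs were higher in full serum for 20 of 22 genes, by a median of 0.19, and none was called (camera adjusted p = 1.97e-05, and adjusted p = 0.166 with an estimated correlation). The 3 fibroblast marker genes tested were also higher, FN1 by 0.42, VIM by 0.15 and THY1 by 0.13, with none called (camera adjusted p = 0.024, and adjusted p = 0.18 with an estimated correlation). That list's adjusted p was 0.0954 without charcoal vehicle replicate 1 and 0.115 without full-serum vehicle replicate 1, and without the latter VIM stood at -0.068 and FN1 at 0.66. Without full-serum vehicle replicate 2 they stood at 0.37 and 0.18, and FN1 at 0.27 without charcoal vehicle replicate 1. VIM stood at 0.27, THY1 at 0.34 and the small RNA median at 0.379 with the offset of 16 subtracted.

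**Figure D1:**
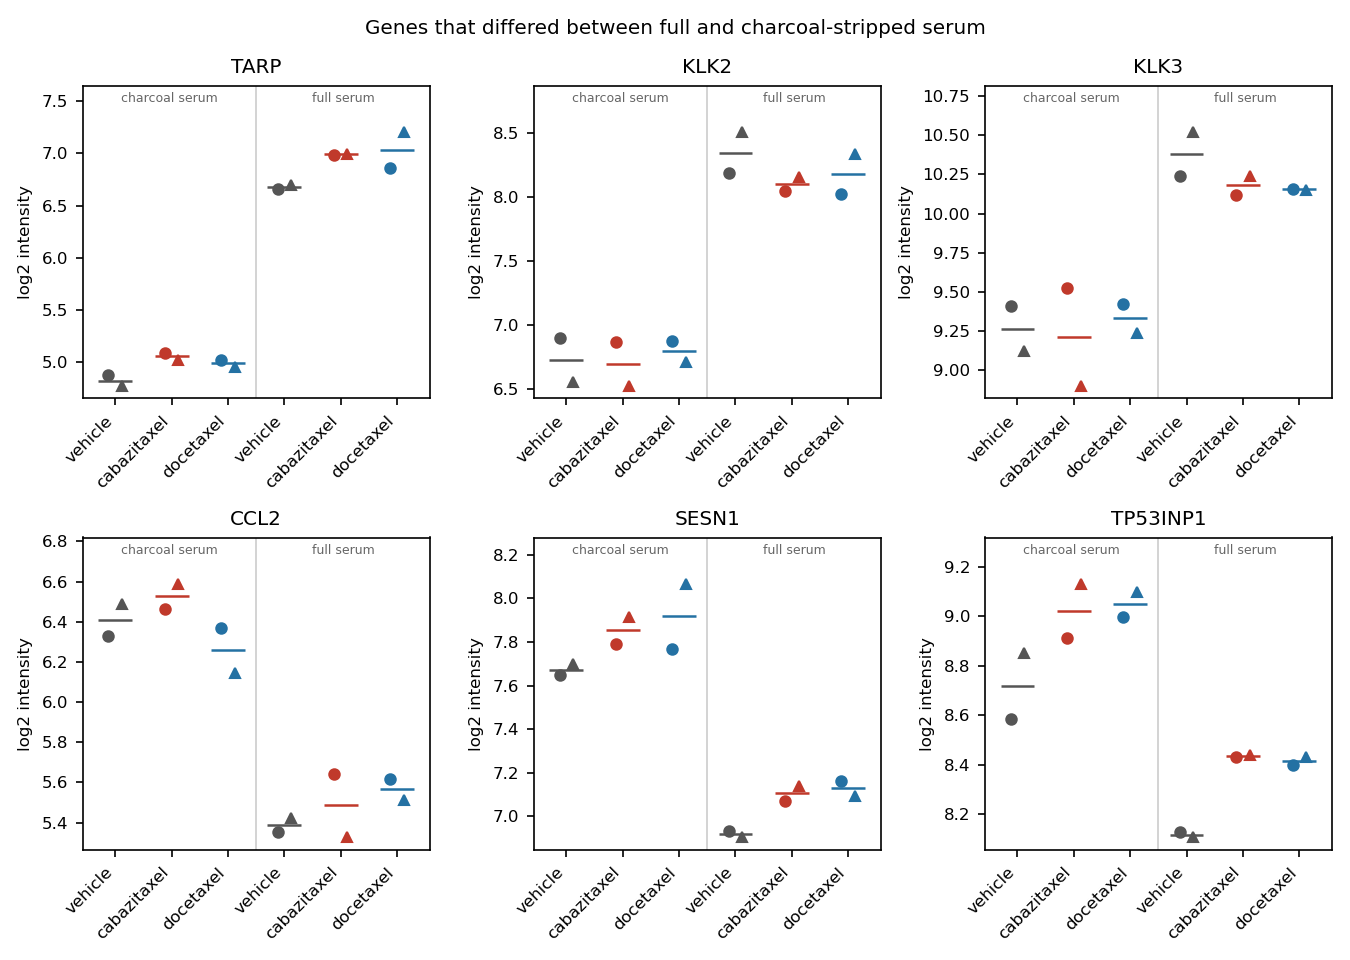
Log2 intensity (vertical axes) of 6 genes named for the serum comparison on each of the 12 arrays, grouped by treatment and serum (horizontal axes). Points are arrays (circles replicate 1, triangles replicate 2) and bars are means of 2 arrays. TARP stood at 4.82 in charcoal and 6.68 in full serum with vehicle, and CCL2 at 6.41 and 5.39.

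Each taxane was compared with vehicle, as the series' design does, first as the mean of both sera. With cabazitaxel, all 31 DNA replication genes tested were lower, with a median log2 change of -0.186. They included the helicase genes MCM5 (-0.45, SE 0.104) and MCM3 (-0.29, SE 0.0619), the G1/S cyclin gene CCNE2 (-0.24, SE 0.0462), and MCM10 (-0.41, SE 0.0835). Limma called 0 of them over all genes (adjusted p from 0.74 for MCM10 and CCNE2), and adjusted over the list alone 16 were lower. The list had a camera adjusted p of 2.19e-27 but an adjusted p = 0.127 with an estimated correlation, and fry gave 0.0716. In each serum, each vehicle array had a higher mean of the list than each taxane array.

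DNA repair genes were lower with cabazitaxel for 18 of 22, by a median of -0.0681, with EXO1 (-0.30) and XRCC2 (-0.25), which serve recombination and mismatch repair, lower when adjusted over the list alone (camera adjusted p = 1.27e-05, and adjusted p = 0.127 with an estimated correlation). Among 20 p53 target genes, 14 were higher, by a median of 0.0658 (camera adjusted p = 0.0105, and adjusted p = 0.304 with an estimated correlation). TP53INP1, a p53-inducible gene of cell death and autophagy, had a log2 change of 0.31 and was the single p53 target higher when adjusted over the list alone, PLK2 had 0.16 and SESN1 0.18. Mitosis genes were lower for 22 of 36, by a median of -0.0491, with MELK at -0.21, the cohesin protector SGO1 at -0.21 and cyclin B2 (CCNB2) at 0.15, and adjusted over the list alone 0 passed (camera adjusted p = 0.0178, and adjusted p = 0.861 with an estimated correlation). The p53 list's adjusted p was 0.162 without charcoal cabazitaxel replicate 2 and 0.108 without full-serum vehicle replicate 2. The mitosis list's was 0.0594 without charcoal vehicle replicate 2, 0.364 without charcoal cabazitaxel replicate 1, 0.108 without full-serum vehicle replicate 2 and 0.209 without full-serum cabazitaxel replicate 2. It was also 0.0539 on the scale with the offset subtracted, where the p53 median was 0.101 and PLK2 stood at 0.25.

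Limma called 0 genes with cabazitaxel, and 520 had an unadjusted p under 0.05. The genes with the smallest p, which did not pass, were, upward, the metallothionein gene MT1G (0.41, 95% confidence interval 0.26 to 0.56), TP53INP1 (0.31), MORN4 (0.26), APOO (0.37) and SBSN (0.24), and, downward, WDR76 (-0.37, 95% confidence interval -0.51 to -0.22), CCNE2 (-0.24), OGFR (-0.29), ZNF850 (-0.39) and MCM10 (-0.41). SBSN stood at 0.51, OGFR at -0.53 and ZNF850 at -0.69 with the offset of 16 subtracted.

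Docetaxel was set against the same vehicle arrays as cabazitaxel, in each serum and in their mean. Changes that both drugs share are therefore not independent results, and noise in those arrays alone can give such agreement. With docetaxel, the same list of DNA replication genes was lower for 29 of 31, by a median of -0.173. Examples were MCM10 (-0.35, SE 0.0835), CDC45 (-0.28, SE 0.0631), the polymerase clamp gene PCNA (-0.21, SE 0.0507) and CCNE2 (-0.18, SE 0.0462). Limma called 0 of them over all genes (adjusted p = 0.757 for each of these 4), and adjusted over the list alone 12 were lower. The camera adjusted p was 9.2e-19, with an adjusted p = 0.259 with an estimated correlation, and fry gave 0.0862. Of 20 p53 target genes, 18 were higher, by a median of 0.0749, and adjusted over the list alone TP53INP1 (0.31), SESN1 (0.23) and SPATA18 (0.20), a gene of mitochondrial quality control, were higher (camera adjusted p = 0.00227, and adjusted p = 0.259 with an estimated correlation). Without full-serum vehicle replicate 2 that list's adjusted p was 0.0538. Mitosis genes were higher for 24 of 36, by a median of 0.0552, with CCNB2 at 0.18, and the list did not pass (camera adjusted p = 0.417). Subtracting the offset gave a p53 median of 0.132, a mitosis median of 0.0838 and 0.35 for SPATA18.

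Limma called 0 genes with docetaxel, and 672 had an unadjusted p under 0.05, 448 of them higher. The genes with the smallest p, which did not pass, were, upward, MORN4 (0.33), BLTP3A (0.35), ZBTB41 (0.28), ZNF208 (0.42) and the thioredoxin inhibitor gene TXNIP (0.27), and, downward, WDR76 (-0.33), CDC45 (-0.28), MCM10 (-0.35), PCNA (-0.21) and HASPIN (-0.37), a mitotic histone kinase gene. ZNF208 stood at 0.76 with the offset of 16 subtracted.

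Androgen-induced genes did not pass with either drug, with a median log2 change of -0.0015 for cabazitaxel (camera adjusted p = 0.862) and 0.0387 for docetaxel (camera adjusted p = 0.479). The 27 microtubule-associated genes had medians of 0.0121 (camera adjusted p = 0.816) and 0.0264 (camera adjusted p = 0.944), with MAP1B, which binds microtubules in neurons, at 0.37 for docetaxel. The 18 apoptosis regulators had medians of -0.00266 (camera adjusted p = 0.658) and 0.0295 (camera adjusted p = 0.602), with BIK, a cell death gene, at 0.22 for cabazitaxel. The 16 genes of cholesterol synthesis had medians of -0.0435 (camera adjusted p = 0.212) and -0.0134 (camera adjusted p = 0.479). Over the 6 comparisons of a drug with vehicle, KLK3, FKBP5, CCNB1, PLK1, MKI67 and HMGCS1 had log2 changes from -0.27 (MKI67, docetaxel in full serum) to 0.25 (CCNB1, docetaxel in full serum), and limma called none. The lowest of these changes was -0.42 without charcoal vehicle replicate 1, -0.45 without charcoal cabazitaxel replicate 2 and -0.50 without full-serum vehicle replicate 1, the highest was 0.38 without charcoal vehicle replicate 2, and MAP1B stood at 0.24 without charcoal docetaxel replicate 2.

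**Figure D2:**
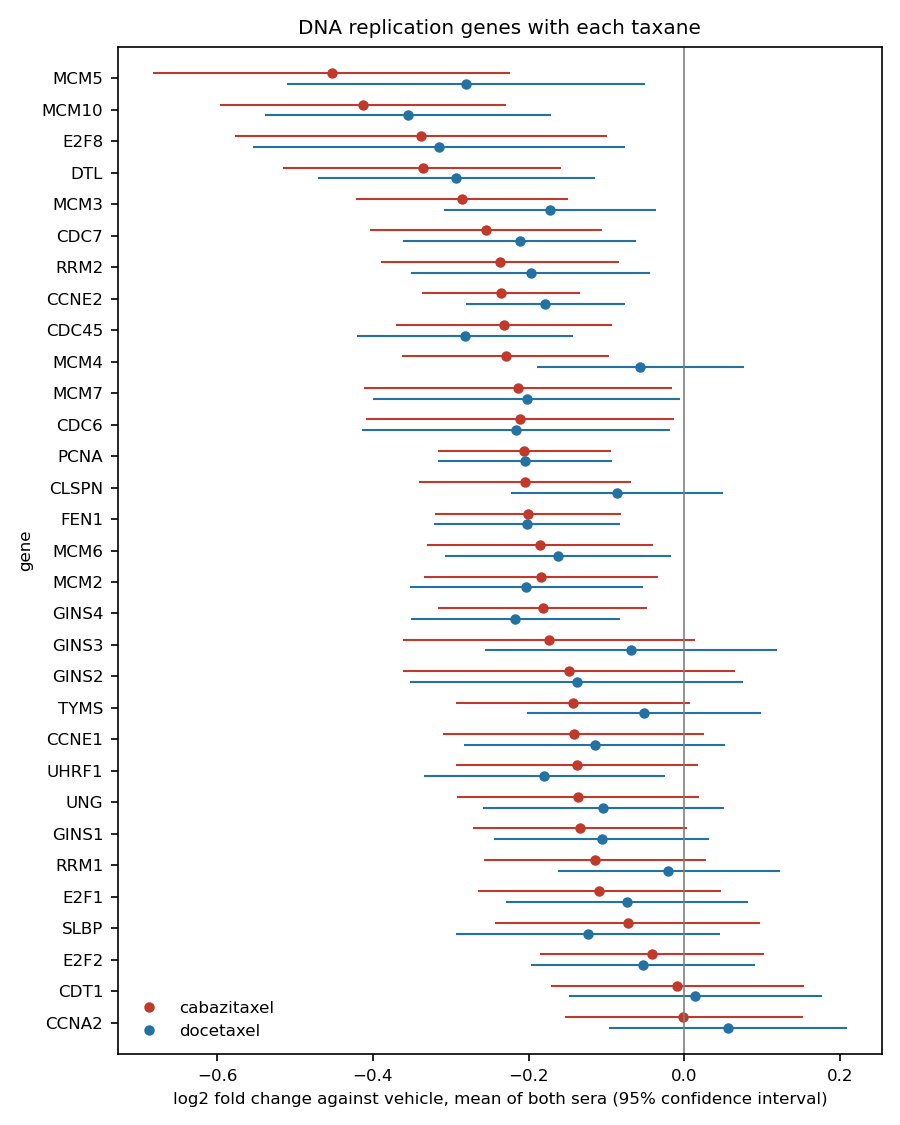
Log2 fold change against vehicle, as the mean of both sera (horizontal axis), of the 31 DNA replication genes tested (vertical axis), for cabazitaxel (red) and docetaxel (blue). Points are limma estimates from 4 arrays against 4 and lines are 95% confidence intervals. The medians were -0.186 and -0.173.

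Within charcoal serum, the DNA replication genes were lower with cabazitaxel for 30 of 31 (median -0.233) and with docetaxel for 29 of 31 (median -0.214). MCM10 stood at -0.53 and -0.43, CCNE2 at -0.33 and -0.26, and PCNA at -0.30 and -0.37. Adjusted over the list alone, 13 and 7 genes were lower, and over all genes 0. The camera adjusted p were 7.57e-22 and 8.81e-16, with an adjusted p = 0.117 and an adjusted p = 0.475 with an estimated correlation. With cabazitaxel, DNA repair genes were lower for 20 of 22, with EXO1 at -0.31 and XRCC2 at -0.24 (median -0.105, camera adjusted p = 2.91e-06, and adjusted p = 0.117 with an estimated correlation). Mitosis genes were lower for 26 of 36, with CDCA3 at -0.39 and MELK at -0.20 (median -0.0723, camera adjusted p = 0.0179, and adjusted p = 0.87 with an estimated correlation). The mitosis list's adjusted p was 0.0815, 0.114 and 0.508 without charcoal vehicle replicate 1, charcoal vehicle replicate 2 and charcoal cabazitaxel replicate 1. CDCA3 stood at -0.24 without the last of these, and MCM10 with docetaxel at -0.23 without charcoal docetaxel replicate 2. Subtracting the offset gave the mitosis list an adjusted p of 0.0649 and the repair list a median of -0.186.

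Limma called 0 genes with either drug in charcoal serum, and 466 with cabazitaxel and 567 with docetaxel had an unadjusted p under 0.05. The genes with the smallest p, which did not pass, were BIK (0.45), MT1G (0.46), CCNE2 (-0.33) and ZNF701 (-0.47) for cabazitaxel, and NKAP (0.46), ZNF208 (0.75), PCNA (-0.37) and PLAGL2 (-0.32) for docetaxel. ZNF701 stood at -1.03 and ZNF208 at 1.36 with the offset of 16 subtracted.

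Within full serum, the DNA replication genes were lower with cabazitaxel for 28 of 31 (median -0.143) and with docetaxel for 23 of 31 (median -0.11). CDC45 stood at -0.32 and -0.38 and CLSPN at -0.32 and -0.27, and MCM5 at -0.53 with cabazitaxel. Adjusted over the list alone, 3 genes and 1 gene were lower, and over all genes 0. The camera adjusted p were 7.62e-11 and 6.1e-07, with an adjusted p = 0.328 and an adjusted p = 0.544 with an estimated correlation. The p53 target genes were higher for 17 of 20 with each drug, with TP53INP1 at 0.32 and 0.30 (medians 0.117 and 0.0991, camera adjusted p = 0.000369 and 0.0223, and adjusted p = 0.328 and 0.544 with an estimated correlation). The small RNAs were lower for 19 and 17 of 22, with SCARNA7 at -0.49 for cabazitaxel and SCARNA22 at -0.75 for docetaxel (medians -0.194 and -0.121, camera adjusted p = 0.000196 and 0.000977, and adjusted p = 0.328 and 0.544 with an estimated correlation). Without full-serum vehicle replicate 2, the p53 adjusted p became 0.0659 and 0.303 and the small RNA ones 0.129 and 0.303. Without full-serum cabazitaxel replicate 2 the small RNA adjusted p for cabazitaxel was 0.169, and without full-serum docetaxel replicate 1 the values for docetaxel were 0.292 (p53) and 0.349 (small RNAs). SCARNA7 with cabazitaxel stood at -0.76 without full-serum cabazitaxel replicate 1, -0.23 without full-serum cabazitaxel replicate 2 and -0.28 without full-serum vehicle replicate 2. Subtracting the offset put it at -0.85, the p53 medians at 0.199 and 0.183 and the small RNA median with docetaxel at -0.305.

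Limma called 0 genes with either drug in full serum, and 446 with cabazitaxel and 578 with docetaxel had an unadjusted p under 0.05. The smallest limma adjusted p with cabazitaxel, 0.446, lay among small RNA or uncharacterised symbols, which the naming rule leaves out. Outside such symbols, the genes with the smallest p did not pass. For cabazitaxel they were SKA2 (0.38), a spindle attachment gene, ZNF737 (0.45), SNX16 (-0.56) and ZNF850 (-0.57). For docetaxel they were ZBTB41 (0.44), FBXO28 (0.37), HPS1 (-0.34) and NYX (-0.32). SNX16 stood at -0.96, ZNF850 at -0.99, HPS1 at -0.79 and NYX at -0.74 with the offset of 16 subtracted. The test in the submitters' notes, at an unadjusted p and without correction, gave 431 and 492 genes for cabazitaxel and docetaxel in charcoal serum and 478 and 515 in full serum, each under the 555 of chance, and 0 after Benjamini-Hochberg adjustment.

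**Figure D3:**
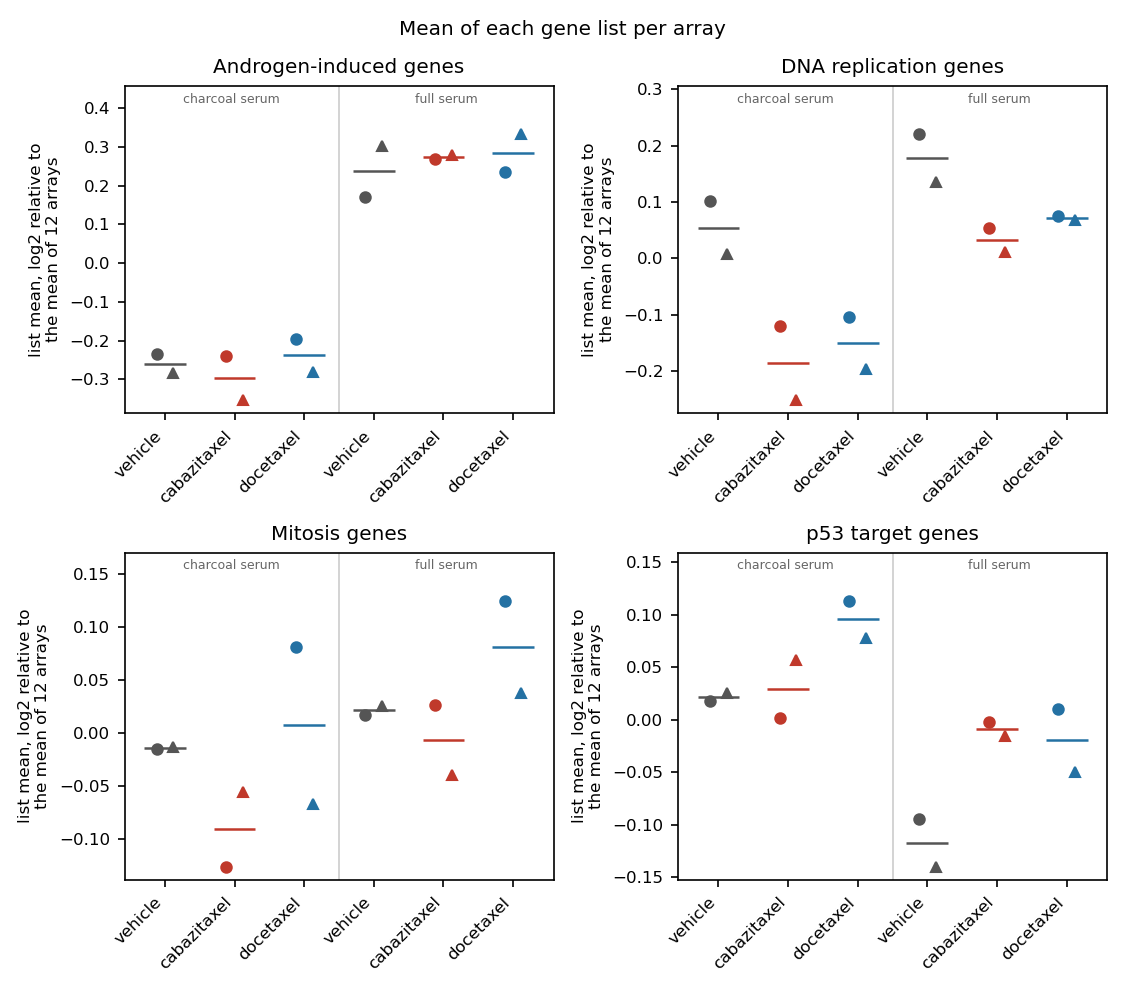
Mean log2 value of 4 gene lists on each of the 12 arrays, relative to the mean of the 12 arrays (vertical axes), by treatment and serum (horizontal axes). Points are arrays (circles replicate 1, triangles replicate 2) and bars are means of 2 arrays. For DNA replication genes, the vehicle arrays lay at 0.101 and 0.00823 in charcoal serum and 0.22 and 0.135 in full serum, above each taxane array of their serum.

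The taxanes were compared directly at the same dose and time. Mitosis genes were lower with cabazitaxel than with docetaxel for 34 of 36 as the mean of both sera, by a median of -0.0806. KIF4A (-0.31, 95% confidence interval -0.47 to -0.15), a chromosome-bound kinesin gene, was lower when adjusted over the list alone (adjusted p = 0.0451 by limma), and KIF14 (-0.28), SGO1 (-0.21) and MELK (-0.14) followed without passing. The camera adjusted p was 3.37e-05, with an adjusted p = 0.771 with an estimated correlation, and fry gave 0.551. DNA repair genes were lower for 17 of 22, with RAD51AP1 at -0.16 (median -0.0766, camera adjusted p = 0.0146, and adjusted p = 0.771 with an estimated correlation). Chromatin modifier genes were lower for 28 of 33, with the demethylating enzyme gene TET2 at -0.12 (median -0.0621, camera adjusted p = 0.025, and adjusted p = 0.879 with an estimated correlation). The repair list's adjusted p was 0.0532, 0.0746 and 0.229 without charcoal cabazitaxel replicate 2, charcoal docetaxel replicate 2 and full-serum docetaxel replicate 1, and the chromatin list's was 0.448, 0.301, 0.408 and 0.26 without charcoal cabazitaxel replicate 1, charcoal docetaxel replicate 2, full-serum cabazitaxel replicate 1 and full-serum docetaxel replicate 2. With the offset of 16 subtracted, the repair and chromatin lists' adjusted p were each 0.0577 and TET2 stood at -0.22.

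Limma called 0 genes between the drugs as the mean of both sera, and 506 had an unadjusted p under 0.05. The smallest limma adjusted p, 0.244, lay among small RNA or uncharacterised symbols, which the naming rule leaves out. Outside such symbols, the genes with the smallest p did not pass (limma adjusted p = 0.958 for each). Upward with cabazitaxel they were GSTT2 (0.22), a glutathione transferase gene, CDRT15 (0.26), SFT2D1 (0.19), STPG3 (0.22) and HCRT (0.20). Downward they were SMC5-DT (-0.27), ZNF445 (-0.29), SOCS6 (-0.27), KIF4A (-0.31) and CERS5 (-0.20), a ceramide synthase gene. The 95% confidence interval of the difference lay within 1.5-fold either way for 99.6% of genes, with a median distance from the estimate to each bound of 0.146 log2. With the offset of 16 subtracted, this share was 86.6% and the distance 0.279, and GSTT2 stood at 0.48, CDRT15 at 0.52, STPG3 at 0.43, HCRT at 0.39, SMC5-DT at -0.59 and CERS5 at -0.41. Without that subtraction, the interval for MCM10 ran from -0.24 to 0.13, for CCNE2 from -0.16 to 0.04 and for TP53INP1 from -0.16 to 0.15.

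In charcoal serum, mitosis genes were lower with cabazitaxel than with docetaxel for 29 of 36, with KIF4A at -0.45 (adjusted p = 0.0344 by limma when adjusted over the list alone) and KIF14 at -0.37 (median -0.0919, camera adjusted p = 0.00274, and adjusted p = 0.884 with an estimated correlation). DNA repair genes were lower for 19 of 22 (median -0.0902, camera adjusted p = 0.00274, and adjusted p = 0.814 with an estimated correlation) and chromatin modifier genes for 28 of 33 (median -0.0973, camera adjusted p = 0.00274, and adjusted p = 0.884 with an estimated correlation). In full serum, mitosis genes were lower for 25 of 36, with SGO1 at -0.38 and BIRC5, a mitotic and survival gene, at -0.22 (median -0.122, camera adjusted p = 0.0226, and adjusted p = 0.805 with an estimated correlation). The mitosis list's adjusted p in charcoal serum was 0.219 and 0.583 without charcoal cabazitaxel replicate 1 and charcoal docetaxel replicate 1, and in full serum 0.374 and 0.506 without full-serum cabazitaxel replicate 2 and full-serum docetaxel replicate 1. BIRC5 in full serum stood at -0.054 without full-serum cabazitaxel replicate 2 and -0.38 without full-serum cabazitaxel replicate 1. The mitosis list's adjusted p in full serum was 0.17 with the offset of 16 subtracted. The chromatin list's in charcoal serum was 0.632 and 0.238 without charcoal cabazitaxel replicate 1 and charcoal docetaxel replicate 2.

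Limma called 0 genes between the drugs in either serum, with 601 genes at an unadjusted p under 0.05 in charcoal and 314 in full serum, and the test in the submitters' notes gave 554 and 455 without correction and 0 after it. The genes with the smallest p, which did not pass, were CDRT15 (0.47), GSTT2 (0.35), SMC5-DT (-0.46) and ZNF17 (-0.36) in charcoal serum, and APOOP5 (0.36), MSRB1 (0.33), GALNT2 (-0.37) and AGPS (-0.36) in full serum. The confidence interval lay within 1.5-fold for 97.1% and 98% of genes, and for 57.2% and 62.2% with the offset of 16 subtracted. On that scale CDRT15 stood at 0.96, GSTT2 at 0.76, SMC5-DT at -0.99 and ZNF17 at -0.87 in charcoal serum, with adjusted p of 0.264 or more, and APOOP5 at 1.31 and MSRB1 at 0.74 in full serum. With all transcript clusters tested, 1 cluster with no gene name (16681891) was called in charcoal serum, at a log2 difference of 0.98 (limma adjusted p = 0.0025).

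The interactions asked whether a drug's effect differed between the sera. For cabazitaxel, the genes with the smallest p were ZNF701 (0.67) and EIF5A2 (0.51), with a more positive change in full serum, and CCDC87 (-0.49) and ADAMTSL4 (-0.50), with a more negative one. For docetaxel they were EIF5A2 (0.60), a translation factor gene, TMEM86A (0.47), NKAP (-0.46) and QSOX2 (-0.41). None of these passed, limma called 0 genes for either drug, and 380 genes for cabazitaxel and 401 for docetaxel had an unadjusted p under 0.05. The median distance from the estimate to each bound of the 95% confidence interval was 0.291 log2, which left room for differences of that size. With the offset of 16 subtracted, it was 0.557, and ZNF701 stood at 1.41, CCDC87 at -1.07, ADAMTSL4 at -1.30 and TMEM86A at 0.92. The DNA replication genes had a median difference between the sera of 0.135 for cabazitaxel (camera adjusted p = 0.0729) and 0.129 for docetaxel (camera adjusted p = 0.103), and the list did not pass. Small RNAs, which had a more negative change in full serum for 18 and 19 of 22 genes, passed by camera (medians -0.223 and -0.238, adjusted p = 0.000898 and 0.00123), and not with an estimated correlation (adjusted p = 0.599 and 0.827). For cabazitaxel the list's adjusted p was 0.079 without full-serum cabazitaxel replicate 2, and for docetaxel it was 0.255, 0.0839 and 0.196 without charcoal docetaxel replicate 2, full-serum vehicle replicate 2 and full-serum docetaxel replicate 1. The small RNA medians were -0.55 and -0.375 with the offset of 16 subtracted.

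Across genes, which are not independent replicates, the effects of cabazitaxel and docetaxel as the mean of both sera correlated with r = 0.532 (Spearman 0.491) and a covariance of 0.00355. The drugs shared their 4 vehicle arrays, and simulated groups with no drug effect and the same sharing gave a mean r of 0.488 and a covariance of 0.00346. With the vehicle arrays split between the drugs by replicate number, r was 0.0171 in 1 assignment and -0.216 in the other. The effects of a drug in charcoal and in full serum, which share no arrays, correlated with r = 0.0732 for cabazitaxel (Spearman 0.0615, simulated mean r 0.0125) and r = 0.101 for docetaxel (Spearman 0.109, simulated mean r -0.0525). Here the simulated ranges were -0.724 to 0.753 for cabazitaxel and -0.796 to 0.702 for docetaxel. With ranges this wide, the correlations cannot decide whether the drugs, or the sera, share an effect. Single arrays moved the observed correlations. The r between the drugs was 0.325 without charcoal cabazitaxel replicate 2, and the r between sera for cabazitaxel was 0.0474 and 0.0444 without charcoal and full-serum vehicle replicate 2. For docetaxel it was -0.0735 and 0.238 without full-serum vehicle replicates 1 and 2, 0.0218 and 0.158 without charcoal docetaxel replicates 1 and 2, and 0.0654 without full-serum docetaxel replicate 2. The r between sera was 0.0398 for cabazitaxel and 0.0653 for docetaxel with the offset of 16 subtracted.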

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

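The tests weighed in this part were chosen after the result was seen, and the list tests themselves were planned. Small RNA genes, mostly small Cajal body RNAs, had a drug effect that differed between the sera by the interaction test, with a camera adjusted p of 0.000898 for cabazitaxel and 0.00123 for docetaxel. With an estimated correlation the adjusted p was 0.599 and 0.827, and by fry it was 0.462 and 0.865, and limma called 0 of the 22 genes. The list's mean stood at -0.141 and -0.0355 on the charcoal vehicle arrays and at 0.0945 and 0.193 on the full-serum vehicle arrays, relative to all arrays, and between -0.12 and 0.0634 on the 8 taxane arrays.

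Array noise shared by the small RNA genes stays open. Exchanging vehicle and taxane labels within each serum gave an exact permutation p of 0.0222 for a difference of -0.244 in the list's mean. It became 0.374 after adjustment over the 28 lists. The smallest p of the 225 arrangements, 0.00444, cannot pass this adjustment for a list alone, so the adjusted value decides nothing. The unadjusted p leaves noise open, since the list was picked among the 28. A single array as the source also stays open, since the median difference, -0.222 with all arrays, was -0.144 without charcoal docetaxel replicate 2, and the medians with 1 array left out had an SD of 0.052. These explanations and a serum-dependent response to the taxanes cannot be told apart with 2 arrays per group.

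Transcript clusters with no gene name were outside the gene comparisons, and limma called 26 of them between full and charcoal serum in vehicle-treated cells. Of these, 19 were higher and 7 lower in full serum, with log2 changes from -0.97 to 2.04, among 13812 such clusters tested. The same fit, over 25724 clusters, called 27 clusters with a gene name, against 44 genes in the reported fit.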

How the results depend on the processing

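The alternatives set before the data were examined were each run, and the log2 of the value minus 16, the mean of 3 treatments, either taxane and the exact permutation tests were chosen after seeing the data. With the fits that left out 1 array set apart, 130 of the counts of called genes stayed within 1.5 times of the reported count and 14 did not. Some counts also moved further than that with 1 array left out. The counts of 0 for the drug comparisons stayed at 0 except under the test in the submitters' notes without correction, which gave 431 (cabazitaxel) and 492 (docetaxel) against vehicle in charcoal serum, 478 and 515 in full serum, and 554 and 455 between the drugs, and with all transcript clusters, which gave 1 between the drugs in charcoal serum because more features were tested. For full against charcoal serum with vehicle (44 genes), the count was 1 with only the 4 vehicle arrays in the fit, which leaves 2 residual degrees of freedom, 70 with a replicate block, all 44 among them, 16 with the offset of 16 subtracted, 621 under the submitters' test without correction and 0 with it, and 256 as the mean of 3 treatments, all 44 among them. Leaving out 1 array gave 7 to 43 genes. The count of 256 became 132 with the offset subtracted and 149 to 248 with 1 array left out. Where an array left a group with 1, that array was assumed to vary like the other groups.

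Camera made 32 list calls over the 12 comparisons, 0 with an estimated correlation and 6 by fry. The adjusted p of the DNA replication list with an estimated correlation and by fry was 0.117 and 0.0813 for cabazitaxel and 0.475 and 0.172 for docetaxel in charcoal serum, 0.328 and 0.43, and 0.544 and 0.435, in full serum, and 0.127 and 0.0716, and 0.259 and 0.0862, as the mean of both sera. The androgen-induced list had 0.0634 with an estimated correlation. The mitosis list between the drugs had 0.884 and 0.859 in charcoal serum, 0.805 and 0.807 in full serum and 0.771 and 0.551 as the mean. In charcoal serum it also lost its call with the stricter filter (0.0952), repeated quantile normalisation (0.119) and with 1 array left out (3.12e-06 to 0.583), and in full serum with the stricter filter (0.0757), quantile normalisation (0.202), the offset subtracted (0.17) and with 1 array left out (0.000559 to 0.506). Over the list results, again with the fits that left out 1 array set apart, 181 stayed on the same side of the threshold. Another 81 lost their call, with the direction kept. Leaving out 1 array took the call from further list results and from named genes. VIM between the sera ran from -0.068 to 0.37 with 1 array left out, and the other named genes kept their direction under each setting run. With the offset subtracted, 19 of the values of named genes called between the sera lost their call. The correlations of effects moved by less than the SD of simulated values under each setting, which is wide (0.284 between the drugs, 0.377 for cabazitaxel and 0.382 for docetaxel between the sera), and that for docetaxel turned to -0.0735 without full-serum vehicle replicate 1. Unless stated, the cause was not tested.

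Arrays with the same replicate number deviated together in part. Their deviations from the group means correlated across genes by over 0.1 in 10 of 15 pairs of groups, from -0.049 to 0.33. The labels do not say that a number marks a shared culture or day, and not all pairs lay over 0.1, so the number was not used as a block in the reported fit. For the DNA replication list, replicate 1 lay above replicate 2 in 6 of 6 groups, and 8 of 8 differences between a taxane and a vehicle array of the same serum and number were below 0, from -0.26 to -0.0658. Exchanging labels within serum and number gave an exact permutation p of 0.0123, the smallest that 81 arrangements can give, and 0.344 after adjustment over the lists. A list alone at that smallest p cannot pass the adjustment, so the adjusted value decides nothing. The floor of the values limits what weakly expressed genes can show, since log2 4.48 is the median of the table and also the filter's bound.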

Other observations

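The serum comparison over 3 treatments, the exact tests of list means and the weighing of both taxane patterns were chosen after the result was seen. Counts of other splits were planned as a test. For the serum comparison over 3 treatments and for either taxane, they were run on comparisons added after seeing the data. Averaged over vehicle, cabazitaxel and docetaxel, full serum raised or lowered 256 genes against charcoal serum by limma, 122 higher and 134 lower. The androgen-induced genes were higher for 20 of 20, by a median log2 of 0.494, and 15 were called over all genes and 17 adjusted over the list alone. KLK2 rose by 1.47, HERC3 by 0.97, KLK3 by 0.97, CENPN by 0.94, FKBP5 by 0.45 and NDRG1, a differentiation and stress gene, by 0.34, and TARP, which is not in the list, rose by 1.94. This list passed with an estimated correlation (camera adjusted p = 0.0278) and by fry (0.000124), and of the androgen-repressed genes CAMK2N1 (-0.35) and DDC (-0.33) were called lower. TLL1 (-0.95), CCL2 (-0.92) and SESN1 (-0.76) were among the largest falls.

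Replication genes were higher in full serum for 30 of 31, by a median of 0.175, with 8 called, among them the origin licensing gene CDC6 (0.52), CLSPN (0.33), CDC45 (0.30) and PCNA (0.22). The camera adjusted p was 1.21e-18, with an adjusted p = 0.115 with an estimated correlation, and fry gave 0.00771. Of DNA repair genes RAD54B (0.57) was called higher and BARD1 (-0.41) lower, of inflammatory genes CCL2, NFKB1 (-0.53) and CCL20 (-0.38) were called lower, of fatty acid genes ELOVL5 (0.57) and ACACA (0.28) higher, and of p53 targets SESN1 and TP53INP1 (-0.61) lower. Exchanging serum labels within each treatment gave the androgen-induced list a difference of 0.53 and the replication list 0.188, each at an exact permutation p of 0.00926, the smallest that the 216 arrangements can give (adjusted p = 0.0324). The androgen-repressed (-0.158), DNA repair (0.0808), p53 (-0.0973), fatty acid (0.119), NF-kappaB (-0.178) and glycolysis lists (0.0794) had the same p, so it does not set the first lists apart, and the fibroblast list had 0.135 at 0.0278 (adjusted p = 0.0865). The count of 256 became 167 without charcoal docetaxel replicate 2, 151 without full-serum cabazitaxel replicate 2, 169 without full-serum docetaxel replicate 1 and 149 without full-serum docetaxel replicate 2, and 20 of the 23 genes tested here by name stayed called with each of the 12 arrays left out, the exceptions being PCNA, DDC and ACACA. With an assumed offset of 16 subtracted, these 3 and CDC45, CAMK2N1 and BARD1 were not called (adjusted p from 0.0532 to 0.192), and FKBP5 stood at 0.92, NDRG1 at 0.57, CCL20 at -0.65 and DDC at -0.53. In a simpler fit with treatment as a term, the real split called 322 genes and the highest of the other splits 3. Only the real split, 1 of 100, was as large. That test treats the 12 arrays as separate units, which the labels do not state, so chance is not excluded as the source of the count. At an unadjusted p under 0.05 the counts were closer, 1550 in the real split and 1517 in the highest other.

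The lower DNA replication genes with either taxane had a difference of -0.174 in the list's mean against vehicle. A single vehicle array is argued against, since the median of -0.174 was -0.147 at the nearest to 0, without full-serum vehicle replicate 1. Array noise shared by these genes stays open. The list's exact permutation p was 0.00444, the smallest that the 225 arrangements can give, and 0.124 after adjustment over the 28 lists. A list alone at that smallest p cannot pass this adjustment, so the adjusted value decides nothing. The unadjusted p leaves noise open, since the list was picked among the 28. The camera adjusted p with an estimated correlation was 0.13, by a test whose rate of missed changes was not measured. A lower share of cycling cells as the whole cause stays open too. The list's mean less that of the mitosis list differed from vehicle by -0.168 (-0.14 with cabazitaxel, -0.195 with docetaxel). The exact permutation p was 0.00444, again the smallest possible, and 0.12 after adjustment over the lists set against the mitosis list. A list alone cannot pass that adjustment either, so the adjusted value decides nothing. The unadjusted p leaves the question open, since the list was picked among them. The mitosis list itself differed by -0.0522 with cabazitaxel and 0.0405 with docetaxel. An effect of the taxanes on these genes was not tested apart from these and stays open.

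The lower mitosis genes with cabazitaxel than with docetaxel rest on less. Exchanging the drug labels within each serum gave an exact permutation p of 0.167 for a difference of -0.0927, and 36 arrangements cannot give less than 0.0556, so shared array noise stays open. The median of -0.0806 was -0.0469 without charcoal docetaxel replicate 1, and the medians with 1 array left out had an SD of 0.0251, so a single array as its source stays open too. A difference between the drugs in mitotic arrest at this dose was not tested by another measure.

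For the drug comparisons as the mean of both sera, limma called 0 genes in the real split, and each of the other splits reaches a count of 0. The 34 of 34 splits as large for cabazitaxel against vehicle, docetaxel against vehicle and cabazitaxel against docetaxel, and the 100 of 100 for either taxane against vehicle, were therefore fixed in advance and decide nothing. The highest other counts were 40, 0, 0 and 1. At an unadjusted p under 0.05 the real splits gave 479, 713, 575 and 638 genes, and the highest of the other splits 1497, 1196, 990 and 1279. The split that called 40 genes parted replicate 1 from replicate 2 in each group of cabazitaxel and vehicle, which points to a structure of these samples by replicate number. With replicate number as a block, cabazitaxel against vehicle still gave 0 genes.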
